A study of Drosophila melanogaster with 2 samples.

How the data were processed

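Anti-GFP chromatin immunoprecipitation was sequenced from transgenic Drosophila embryos that express Twist fused to GFP, as 2 biological replicates of 1 group, per the labels. Chromatin fragments had a size range of 200 to 800, per the labels, which give no unit. Replicate numbers were taken from the labels. The labels describe the embryos as 2 to 12 h old.

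Peak lists in the narrowPeak format were used as the authors deposited them, with coordinates in the dm6 assembly, per the labels. The authors' records that accompany the files say that each replicate's peaks were called against the same control file, that the pooled list was called on the alignments of both replicates, and that the IDR list was derived from the replicate lists and the pooled list. The aligner, the peak caller and their settings are not given in the sources used here. The deposited signal value per peak has no stated scale and was used only to rank peaks within a list. The deposited −log10 q-value reached a ceiling: 32.3% of replicate 1 peaks, 43.3% of replicate 2 peaks and every IDR peak were tied at the highest value, so it could not rank them. Signal tracks and the control file were not used here. The lists hold exactly 30000 peaks each except the IDR list, with 6516, and the lists of 30000 were therefore taken to be limited by number. Most intervals of the replicate lists have 1 fixed width (424 bp for 83.8% of replicate 1 peaks and 436 bp for 84.4% of replicate 2 peaks), so positions were compared by summit. In the IDR list 16.7% of peaks have the most frequent width, 436 bp, and widths range from 109 to 2312 bp. Depth is unknown, so intervals cover the counting of peaks or genes only.

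The sequence was the reference Release 6 assembly and the annotation the Ensembl release of it, with transposable elements left out (18277 genes). Every peak end lay within the length of its chromosome on all 7 chromosomes. Positions are 1-based. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

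N was the number of IDR peaks. Summits were matched within 100 bp. Chance levels came from 1000 circular shifts of the summits along each chromosome, with two-sided empirical p-values of at least 0.0020. Places were assigned in the order promoter (500 bp around a start), coding exon, UTR, other exon, intron, intergenic. Motifs were sought on both strands in 101 bp windows at the summit and in a control window centred 1000 bp away on a randomly drawn side, with an exact McNemar test, and p-values were adjusted by Benjamini-Hochberg over the 10 E-box types, the 8 other motifs or all 2080 6-mers. The 15 gene lists, with 185 entries for 176 genes, were compared with 10000 random sets of the 13968 protein-coding genes matched on locus length in 20 bins, adjusted over the lists, with a threshold of 0.05; the smallest p they allow is 0.0002. All 185 entries were found in the annotation, 5 of them through synonyms. A gene was counted as holding a peak when a summit lay in its body or within 5 kb.

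The tests, the alternatives, the gene lists and the rule for named genes were set before the data were examined, except those that the text says were chosen after the data were seen. The rule named the genes nearest to the 20 highest-signal IDR peaks, the 10 genes with the most summits, every early mesoderm gene, and of each other list the 3 members with the strongest peak and, where fewer than 5, those without any. A gene that this rule would name is not reported here. Alternatives were other matching distances, overlap criteria and list sizes, other promoter, motif and gene windows, other controls, the IDR peaks with the higher signal, and each replicate left out, where the N highest peaks of the other replicate took the place of the IDR list.

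The same code was also tested on simulated data. On shifted summits without a planted motif, 0 of 2080 6-mers passed. With CATATG planted in 10.1% of windows, 1 E-box type passed, with the motif found in 12.4% of windows including those that held it already, and CATATG ranked 1 among the 6-mers. For the replicate overlap, 58.8% of 6516 peaks were found shared where 58.6% were shared by construction. In the gene list test, 0 of 15 lists passed without planted peaks, and with peaks planted at the cardiac mesoderm genes 1 list passed, the planted one. Shifted summits lack the excess at promoters of the IDR summits, 39.5% against 13.6% in shifts. The simulations therefore do not show how the motif and gene list tests behave for summits rich in promoters.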

Results

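The data came from a chromatin immunoprecipitation experiment with sequencing on Drosophila melanogaster embryos. The embryos carried a transgene that expresses Twist, a basic helix-loop-helix transcription factor of the early mesoderm, fused at its C-terminus to GFP, and the chromatin was precipitated with an antibody against GFP. Whole embryos of mixed sex, collected between 2 and 12 h, were used, so every tissue of the embryo contributed chromatin. There was 1 group with 2 biological replicates. Each replicate had a list of 30000 peaks, as had both replicates pooled, and a list of 6516 peaks passed the authors' threshold on the irreproducible discovery rate (IDR). No other genotype, stage or antibody was compared, so the comparisons were replicate against replicate, and peaks against the rest of the genome. The depth of the libraries is unknown, because peak lists hold no read counts. The signal value of a peak was the authors' own, on a scale that is not stated, and was used only to rank peaks within a list.

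The first question was how far the replicates gave the same sites. The strongest site was the same in both: an intronic peak of Mef2, a transcription factor needed for muscle differentiation, ranked 1 in replicate 1 and 1 in replicate 2. All 20 of the highest-signal IDR peaks lay among the first 50 of each replicate. Those 20 were chosen by signal over both replicates pooled, so their high ranks in each are partly built in. Of the 6516 highest-signal peaks of replicate 1, 4813 had a summit within 100 bp of a summit among the 6516 highest of replicate 2, which is 73.9% (95% Wilson interval 72.8 to 74.9%). Circular shifts of the summits along each chromosome gave 0.992% on average (circular permutation test with 1000 shifts, two-sided p = 0.0020, the smallest that number of shifts allows). Over the full lists 16768 pairs of summits matched, with a median distance of 29 bp, and their signal values had a Spearman rho of 0.793 (1000 permutations, two-sided p = 0.0020, the smallest possible). That correlation is across peaks, which are not independent replicates. Both lists were called against the same control file, which can place shared peaks in both.

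**Figure D1:**
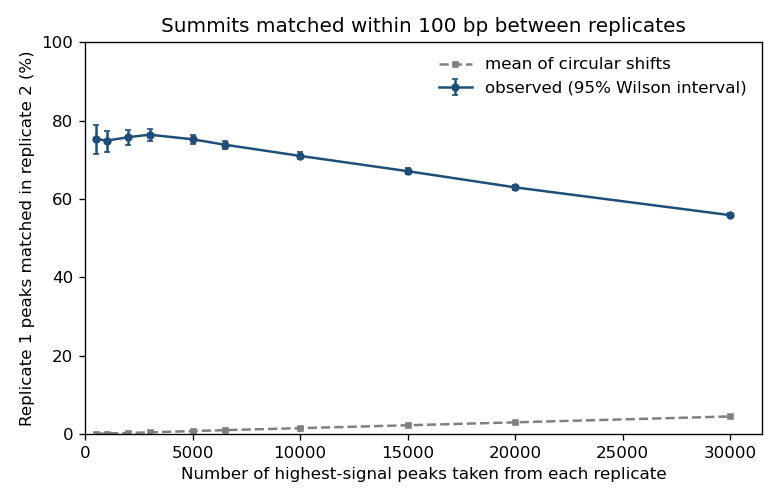
Percent of the highest-signal peaks of replicate 1 with a summit of replicate 2 within 100 bp (vertical axis) against the number of peaks taken from each replicate (horizontal axis); bars are 95% Wilson intervals and the dashed line is the mean of 100 circular shifts. The share was 75.4% for the first 500 peaks and 55.9% for all 30000.

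The 6516 IDR peaks were the highest-signal part of the pooled list, row for row. Of them, 98.5% (95% Wilson interval 98.1 to 98.7%) had a replicate 1 summit within 100 bp, and 96.9% (96.5 to 97.3%) had one of replicate 2, where shifts gave 4.53% and 4.52% (circular permutation, 1000 shifts each, p = 0.0020). The matched peaks sat high in both lists, at a median rank of 3292 in replicate 1 and 3229 in replicate 2. Both replicates held 6218 of the IDR peaks, 198 were in replicate 1 alone, 99 in replicate 2 alone and 1 in neither. Since the IDR list was derived from these same libraries, the high shares describe how the list was built and are not independent evidence.

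The sites with the highest signal lay at genes of several kinds. The strongest IDR peak (chromosome 2R, 9931253 to 9932420, dm6) lay in an intron of Mef2, 2278 bp from its nearest annotated start, and held 2 matches to CACATG within 50 bp of its summit. The next was a promoter peak of the long non-coding RNA gene lncRNA:CR45361 (2L, 20485727 to 20486933), with 3 matches to CACATG. The third lay in an intron of CG11357 (3L, 4546210 to 4547496), and the fourth nearest to lncRNA:CR43234 (2L, 20480891 to 20481848). The nearest starts of the peaks ranked 5 to 20 belonged to an unnamed non-coding transcript inside Tis11, then ph-p, Ocho, Art3, lncRNA:CR9162, CycB, VepD, CG44286, px, net, CG11050, cbt, CG14100, mir-9388, CG9663 and unc-5. Among these 20 peaks, 7 lay in promoters, 8 in introns and 4 between genes, and 10 held CATATG or CACATG within 50 bp of the summit.

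The genes with the most IDR summits in the gene body or within 5 kb were fz2, a Wnt receptor, with 24 summits, CG1677 with 21, jing with 20, RapGAP1, kirre and tara with 19 each, cv-c with 18, hth and SKIP with 17 each, and sbb and MSAmiP, tied for the last place with 16 each. The product of kirre works in myoblast fusion, and hth encodes a homeodomain protein. A longer gene has more room for peaks, so these counts carry no test. A summit was counted for each gene whose window held it, so it need not belong to the gene named. For example, brk lies inside CG1677, and its 2 summits also count for CG1677.

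Of the 13 early mesoderm genes, 12 held an IDR peak; Ilp4, which encodes an insulin-like peptide, held none. Mef2 had 13 summits, Traf4 11, stumps 10, zfh1 9, twi and trbl 7 each, T48 6, tin 5, sna 4, htl and mthl1 (also called mist) 3 each, and fog 2. The strongest peak at twi itself lay downstream of the annotated gene (2R, 23049492 to 23050532, signal rank 61), ranked 70 in replicate 1 and 52 in replicate 2. Its summit was 3651 bp from the nearest annotated start of twi, which lies inside the gene among the other summits. The strongest peak of htl, a fibroblast growth factor receptor of the mesoderm, was intronic (3R, 18049412 to 18050924, rank 80), as was that of Traf4 (2L, 4369924 to 4370625, rank 67). Those of zfh1 (rank 92), stumps (108), T48 (190) and tin (191) were also in introns. The peak of sna ranked 2037, at rank 1586 in replicate 1 and 7096 in replicate 2. Length-matched random sets of 13 genes had 7.89 ± 1.73 genes with a peak (SD over 10000 sets), and the count of 12 did not pass the adjusted threshold (two-sided permutation of genes within length bins, adjusted p = 0.060). The members held 6.15 summits each on average against 1.93 ± 0.744 in random sets (permutation adjusted p = 0.0030). The count of 12 passed with the 3258 highest-signal IDR peaks (permutation adjusted p = 0.0075), with windows of 1 kb (0.0045) and by nearest start (0.0015). It also passed against genes matched on the number of transcription starts in place of length, an alternative chosen after the data were seen (permutation adjusted p = 0.011). It did not pass without replicate 1 (permutation adjusted p = 0.056), without replicate 2 (0.123) or with windows of 10 kb (0.316).

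**Figure D2:**
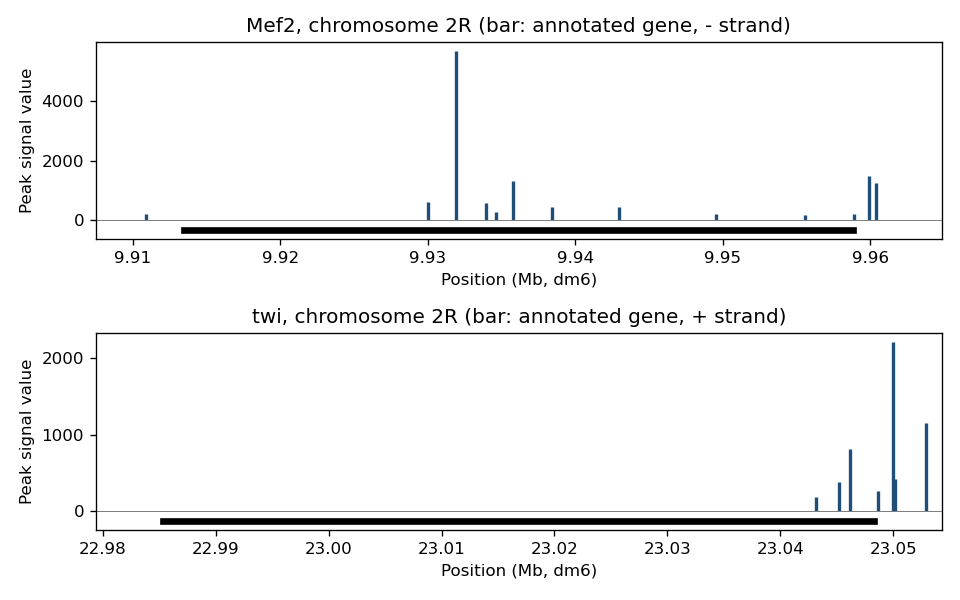
IDR summits at Mef2 and twi: position in Mb of the dm6 assembly (horizontal axis) and the authors' peak signal value (vertical axis, scale not stated); the black bar is the annotated gene. Mef2 has 13 summits, the strongest intronic. The 7 summits of twi are grouped around its downstream end, where an annotated start of twi also lies among them.

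Genes of somatic muscle identity and of the heart held peaks more often than genes of matched length. Of 18 genes of somatic muscle identity and fusion, 17 had a peak against 11.5 ± 2.01 in random sets (permutation adjusted p = 0.017), all but rst; the strongest peaks were at how (rank 48), Six4 (85) and sns (94). All 12 cardiac mesoderm genes had one against 7.06 ± 1.69 (permutation adjusted p = 0.017), led by Him (133) and by Doc2 and Doc3, which share the peak at rank 154. In the list of muscle structural proteins 11 of 18 had a peak, against 11.0 ± 2.06 (permutation adjusted p = 1), with Tm1 (144), Act87E (167) and Mlp84B (262) the strongest. Of 8 visceral mesoderm genes 7 had a peak, all but beat-IIa, against 4.80 ± 1.37 (permutation adjusted p = 0.40), led by bap (91), org-1 (175) and Fas3 (222). Against genes matched on transcription starts in place of length, those 7 passed (2.72 ± 1.33, permutation adjusted p = 0.012). Matching on starts leaves locus length unmatched, here and for the other lists, and a longer gene has more room for peaks. Neighbouring genes share peaks, so members of a list are not fully independent. The call for somatic muscle genes was lost without either replicate (permutation adjusted p = 0.056 without replicate 1 and 0.059 without replicate 2), and that for cardiac genes without replicate 2 (10 of 12, permutation adjusted p = 0.38).

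Peaks were not confined to mesoderm genes. All 12 genes of the neurogenic ectoderm, the tissue beside the mesoderm, had a peak against 7.14 ± 1.68 (permutation adjusted p = 0.017), led by sim (rank 138) and aos (239). Of 17 segmentation genes 15 had one against 9.11 ± 2.03 (permutation adjusted p = 0.017), led by slp2 (342), slp1 (754) and odd (794) and without gt and tll; this call was lost without replicate 2 (13 of 17, permutation adjusted p = 0.33). Of 20 ribosomal protein genes 19 had one against 9.22 ± 2.22 (permutation adjusted p = 0.0030), led by RpL8 (203), RpL3 (279) and RpS27 (441) and without RpS6. The remaining 7 lists did not pass. They were dorsal ectoderm (8 of 10, permutation adjusted p = 0.46; ush, zen and tup strongest, tld and tsg without), endoderm and gut (5 of 7, 1; cad, grn and srp, without GATAe and byn), and trachea (5 of 6, 0.85; bnl, trh and dysf, without btl). Hemocyte genes (5 of 8, 1) were led by ush, Hml and srp, with gcm2, Pvr and lz without a peak, and neural genes (7 of 11, 1) by elav, pros and ase, with brp, para, futsch and wor without. Germline genes (7 of 10, 0.85) were led by vas, bgcn and bam, with pgc, aub and tud without. The spermatid and adult serum or yolk protein genes, a group taken as unrelated to embryonic mesoderm, had the lowest share, 4 of 15 against 7.21 ± 1.92 (permutation adjusted p = 0.34), the strongest at Lsp2, Yp3 and Lsp1beta. By the mean number of summits per member, early mesoderm, somatic muscle, cardiac mesoderm, segmentation and ribosomal protein genes passed (permutation adjusted p = 0.0030, 0.015, 0.022, 0.0030 and 0.0070). Of these calls, that of somatic muscle was lost by nearest start (permutation adjusted p = 0.071), and that of cardiac mesoderm without replicate 2 (0.127) and with windows of 1 kb (0.133). That of ribosomal proteins was lost by nearest start (permutation adjusted p = 0.058) and against genes matched on transcription starts (0.49). With the 3258 highest-signal IDR peaks, early mesoderm alone passed by this measure. Neurogenic and dorsal ectoderm genes passed by nearest start (permutation adjusted p = 0.040 each), and these and visceral mesoderm genes against genes matched on transcription starts (0.00075, 0.0043 and 0.0040). By the number of members with a peak, 1 list, the ribosomal proteins, passed with windows of 10 kb, and 3 lists, early mesoderm, neurogenic ectoderm and ribosomal proteins, passed with the 3258 highest-signal IDR peaks. With windows of 1 kb 6 lists passed, early mesoderm being added. By nearest start 7 passed, with early mesoderm and dorsal ectoderm (8 of 10, permutation adjusted p = 0.016) added, and 7 passed against genes matched on transcription starts, with early and visceral mesoderm added.

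**Figure D3:**
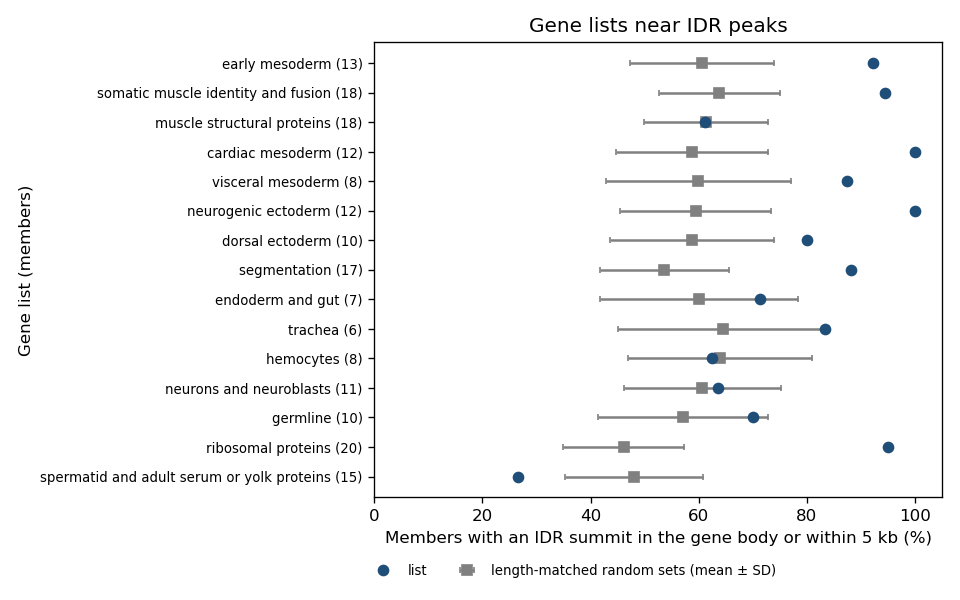
Percent of the members of each of 15 gene lists with an IDR summit in the gene body or within 5 kb (circles, horizontal axis), beside the mean and SD of 10000 length-matched random sets (squares). Ribosomal protein genes lie at 19 of 20 and the spermatid, serum and yolk protein genes at 4 of 15.

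The summits lay at promoters more often than chance and rarely in coding sequence. Within 500 bp of an annotated start lay 2574 of the 6516 summits, 39.5% (95% Wilson interval 38.3 to 40.7%), against 13.6% ± 0.641 (SD) in 1000 circular shifts (two-sided circular permutation p = 0.0020). Coding exons outside promoters held 1.23% against 13.9%, 3' UTRs 0.783% against 4.36% and intergenic sequence 18.4% against 27.4% (circular permutation p = 0.0020 each). Other non-coding exons held 1.21% against 0.823% (circular permutation p = 0.0080). Introns held 38.2% against 39.3% (circular permutation p = 0.28) and 5' UTRs 0.660% against 0.603% (p = 0.62), neither past the threshold. The call for other non-coding exons was lost with the 3258 highest-signal IDR peaks (circular permutation p = 0.084) and with promoters of 1000 bp (p = 0.24). The intron share was past the threshold, below chance, without replicate 2 (36.8% against 39.4%, circular permutation p = 0.012) and with promoters of 1000 bp (32.1% against 36.0%, p = 0.0020). It was above chance, not past the threshold, without replicate 1 (39.9% against 39.3%, circular permutation p = 0.53), with the 3258 highest-signal IDR peaks and with promoters of 250 bp. The direction for 5' UTRs, never past the threshold, also turned under some alternatives. The promoter share was 41.7% in the highest peaks of replicate 1 and 37.2% in those of replicate 2. The shifts ran over the whole assembled length of each chromosome, with no sequence masked. If peaks cannot be called in part of that sequence, the chance levels of all places are affected, by an amount that was not computed.

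**Figure D4:**
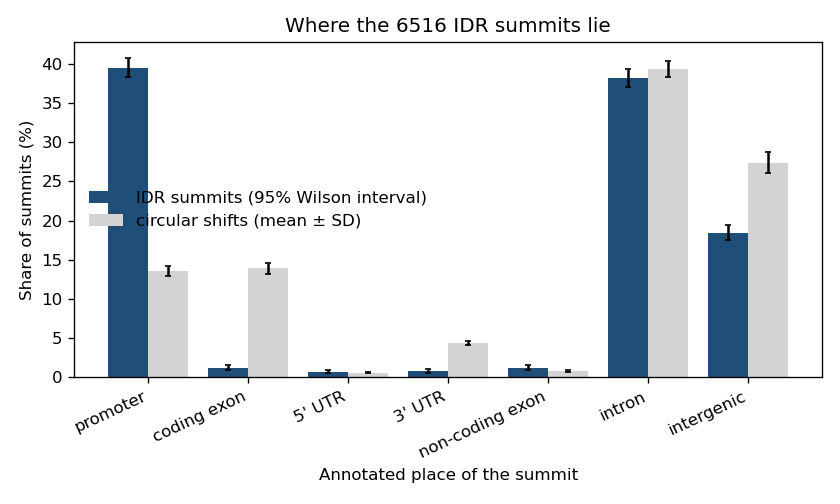
Share of the 6516 IDR summits in each annotated place (dark bars, percent, with 95% Wilson intervals) and the mean and SD of 1000 circular shifts (light bars). Promoters hold 39.5% of summits against 13.6%, and coding exons 1.23% against 13.9%.

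The X chromosome carried 950 of the 6475 summits on the 5 large arms, 14.7% (95% Wilson interval 13.8 to 15.6%). Its share of protein-coding genes was 15.8% (two-sided exact binomial p = 0.010), and its share of chromosome length 17.8% (p = 2.84e-11). The share was 14.8% in replicate 1 and 14.0% in replicate 2. Over all 30000 pooled peaks, an alternative chosen after the data were seen, it was 17.9% (95% Wilson interval 17.5 to 18.3%), above the share of genes (two-sided exact binomial p = 5.62e-22) and not past the threshold against chromosome length (p = 0.51). Peaks are not independent, so these p-values only describe the list.

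E-boxes, the CANNTG sites that basic helix-loop-helix proteins bind, were found at summits more often than 1000 bp away, but the types differed widely. CACATG was within 50 bp of 18.9% of summits (95% Wilson interval 18.0 to 19.9%) against 5.16% of control windows, a ratio of 3.67 (exact McNemar test, Benjamini-Hochberg adjusted over 10 types, p = 1.00e-131). CATATG was at 11.6% against 3.18%, a ratio of 3.64 (exact McNemar adjusted p = 1.92e-78). Then followed CACGTG with a ratio of 2.34, CAGATG with 2.13, CAGCTG with 1.62 and CAAGTG with 1.19, all past the threshold. The order depended on the control: against dinucleotide shuffles CAGCTG had a ratio of 2.90, CACATG 2.64 and CACGTG 1.34. Among summits over 500 bp from a start CACGTG had 1.54. The CAAGTG call was lost with windows of 25 bp (exact McNemar adjusted p = 0.50), with the 3258 highest-signal IDR peaks (0.26) and without replicate 2 (0.18). CAGGTG, a type bound by Snail family repressors, was less frequent at summits, 2.73% against 4.04% (ratio 0.677, exact McNemar adjusted p = 7.28e-05), as were CAATTG (ratio 0.797) and CAACTG (0.859). The CAGGTG call was lost among summits over 500 bp from a start (ratio 0.890, exact McNemar adjusted p = 0.43). That of CAATTG was lost without replicate 1 (exact McNemar adjusted p = 0.11), without replicate 2 (0.068), with windows of 25 or 100 bp (0.18 and 0.58), with controls 500 bp away (0.073) and among summits over 500 bp from a start (0.43). That of CAACTG was lost without replicate 2 (exact McNemar adjusted p = 0.52), with windows of 25 bp (0.88), with the 3258 highest-signal IDR peaks (0.060) and over 500 bp from a start (0.064), and its direction turned against shuffles (ratio 1.05). CAAATG, at 10.3% against 10.7%, did not pass (exact McNemar adjusted p = 0.51), but was more frequent than in shuffles (ratio 1.16, adjusted p = 0.0075). At least 1 of CATATG and CACATG was at 28.2% of summits against 8.12% of control windows.

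**Figure D5:**
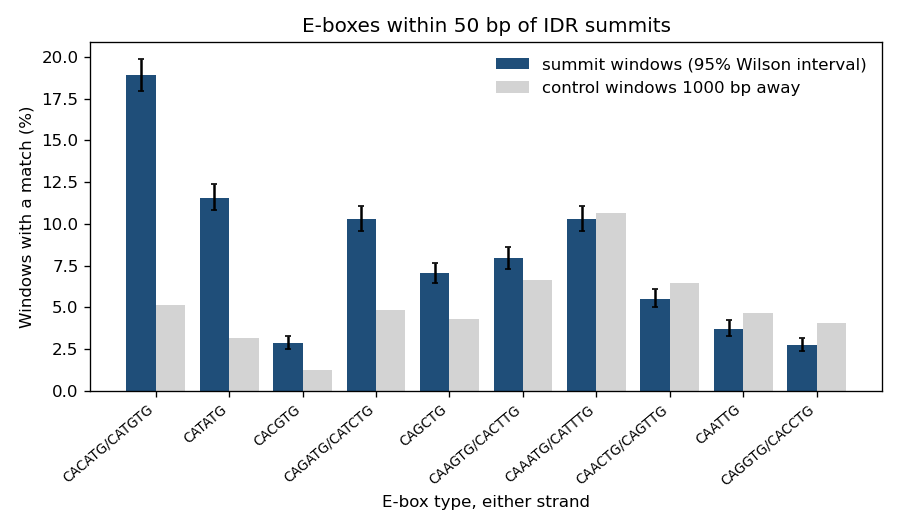
Percent of 6516 IDR summit windows (dark bars, 95% Wilson intervals) and of control windows 1000 bp away (light bars) with each of the 10 E-box types on either strand. CACATG and CATATG show the highest ratios, 3.67 and 3.64, and CAGGTG the lowest, 0.677.

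Of 8 motifs of other embryonic factors, 4 passed the same test. The Mef2 motif had a ratio of 1.67 (5.39% against 3.22%, exact McNemar adjusted p = 1.06e-08), the Tinman motif 1.39 (adjusted p = 0.00028) and the GATA motif 1.16 (adjusted p = 0.0041), while the Bicoid motif was less frequent at summits, with a ratio of 0.793 (adjusted p = 0.043). The Tinman pattern was TCAAGTG or TTAAGTG, and the former contains the E-box CAAGTG, so these 2 results overlap. The motifs of Zelda (ratio 1.36), Dorsal (1.37), GAGA (1.05) and Suppressor of Hairless (1.03) did not pass. Matches were few for Zelda, in 60 summit and 44 control windows, and for Dorsal, in 37 and 27. An enrichment of that size could be missed with so few. The Mef2 call was lost among summits over 500 bp from a start (exact McNemar adjusted p = 0.20), and the Tinman call with windows of 25 bp (0.59). The GATA call was lost with windows of 25 bp (exact McNemar adjusted p = 0.14), with controls 500 bp away (0.16), over 500 bp from a start (0.36) and with the 3258 highest-signal IDR peaks (0.88), and turned against shuffles (ratio 0.911, adjusted p = 0.026). The Bicoid call was lost with windows of 25 bp (exact McNemar adjusted p = 0.30), over 500 bp from a start (0.083) and with the 3258 highest-signal IDR peaks (0.39). Zelda and GAGA passed with windows of 100 bp (exact McNemar adjusted p = 0.015 and 0.0014), and all 8 motifs passed against shuffles, Dorsal with a ratio of 3.08 and Zelda with 2.61. Of all 6-mers tested, 281 were more and 500 less frequent at summits. Leaving out the E-boxes, the 5 with the smallest p among the more frequent were ACATGT (ratio 4.02), ACACAT (2.37), ACATAT (1.88), CACACA (1.83) and AAATAT (1.53). The first 3 of these share bases with CACATG or CATATG. Control windows 1000 bp away were not matched on annotated place, and only 1.23% of summits lay in coding exons outside promoters. Differences in sequence between places may therefore contribute to the motif ratios and to the counts of 6-mers. Controls matched on place were not tested.

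Stronger peaks held these E-boxes more often. CATATG or CACATG was within 50 bp of 39.9% of the 1303 summits with the highest signal (95% Wilson interval 37.3 to 42.6%) and of 23.8% of the 1303 with the lowest (21.6 to 26.2%), a difference of 16.1 percentage points (two-sided Fisher exact p = 1.12e-18). The difference was 12.5 points in replicate 1 and 20.7 in replicate 2. In a comparison chosen after the data were seen, the motifs were at 35.1% of the 3942 summits over 500 bp from a start and at 17.7% of the 2574 promoter summits (two-sided Fisher exact p = 6.06e-55), where their control windows had 8.37% and 7.73%.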

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

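The tests of the ribosomal protein genes were chosen after their count of peaks was seen; the comparison of the unmatched peaks of the replicates, the scaling of X signals and the look at the peaks outside the IDR list were chosen after the data were seen.

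The pooled list holds 23484 peaks that did not pass the IDR threshold and enter no motif or gene comparison above. CATATG or CACATG lay within 50 bp of 14.7% of their summits (95% Wilson interval 14.2 to 15.1%) against 8.14% of their control windows (exact McNemar p = 3.36e-111). The share fell from 32.9% in the first 3000 peaks of the pooled list to 10.1% in the last 3000.

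Of 20 ribosomal protein genes 19 held a peak. A technical candidate explanation is that these genes lie among many transcription starts, with a median of 8 in their windows against 5 for all genes. Against random genes matched on that number, 19 still exceeded 12.6 ± 2.12 (two-sided permutation p = 0.0016), which argues against it as the whole cause of that count. By the mean number of summits per gene, 1.75 against 1.42 ± 0.420 (permutation p = 0.43), the number of starts stays open. Signal at active promoters without a Twist site could also give such peaks: 2 of 16 summits at these promoters held CATATG or CACATG, 12.5% (95% Wilson interval 3.50 to 36.0%), an interval that holds both the 17.7% of all promoter summits and the 7.73% of their control windows, so it cannot be told apart with so few summits; no biological explanation was tested.

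The N highest peaks of one replicate without a partner among the N highest of the other differed in kind. Most were still found lower in the other replicate's full list, 66.8% of those of replicate 1 and 72.5% of those of replicate 2. The 1703 such peaks of replicate 1 held CATATG or CACATG at 13.1% of summits, against 9.51% in control windows, and the 1702 of replicate 2 at 27.6%, against 7.23%. Replicate 1's also lay more often in promoters, 49.5% against 32.7%, which could lower their share. Among summits over 500 bp from a start, replicate 2 was still higher by 14.9 percentage points (95% interval 11.2 to 18.6), which argues against the promoter share as the whole cause. There replicate 1 had 17.3% against 10% in control windows, and replicate 2 32.2% against 7.42%. Within 500 bp of a start, replicate 1 had 8.78% against 9.02%, and replicate 2 18.1% against 6.82%. A difference in depth or enrichment between the libraries stays open, since neither is known, and no biological explanation was tested.

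The X share of IDR peaks, 14.7%, was below the X share of genes, 15.8%, but that of all 30000 pooled peaks, 17.9%, was above it, with 13.2% in the first 3000 and 19.8% in the last 3000. Mixed-sex embryos carry fewer X than autosome copies, which may lower X signals. With X signals multiplied by 4/3 the X share of the N highest pooled peaks was 19.9% (95% Wilson interval 18.9 to 20.9%), above both the share of genes and that of chromosome length, 17.8%. The explanation cannot be told apart from others here, because the scale of the signal and how the control file enters it are not known.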

How the results depend on the processing

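No paired analysis was possible because there was only 1 group. The direction and the side of the threshold held under each alternative run for the replicate overlap, the share of IDR peaks found in each replicate, the promoter, coding exon, 3' UTR and intergenic shares, and the difference between strong and weak peaks. Those of introns, other non-coding exons and 5' UTRs did not all hold. The X share was below those of genes and of chromosome length, and below that of genes with the higher-signal IDR peaks and without either replicate, but above it, at 17.9%, over all 30000 pooled peaks, chosen after seeing the data; the cause was not tested. The replicate overlap ranged from 55.9% (all peaks) to 79.6% (any shared base), and was 73.9% with replicate 2 matched against replicate 1, an alternative chosen after seeing the data. Leaving out each replicate, the promoter share ranged from 37.2 to 41.7%, the X share from 14.0 to 14.8%, the difference in E-box share between strong and weak peaks from 12.5 to 20.7 points, the number of enriched E-box types from 5 to 6 and the number of gene lists past the threshold from 2 to 4. Within promoters, also chosen later, the difference between strong and weak peaks was 7.00 points (two-sided Fisher exact p = 0.0059).

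By the number of members with a peak 5 gene lists passed, but 1 with windows of 10 kb, 3 with the higher-signal IDR peaks, 6 with windows of 1 kb, 7 by nearest start and 7 against genes matched on transcription starts, chosen after seeing the data. By the mean number of summits 5 passed, but 1 with the higher-signal IDR peaks. The cause was not tested. With dinucleotide shuffles as the control, 3 motifs turned: the log2 ratio became 0.22 for CAAATG, 0.070 for CAACTG and -0.14 for GATA. Of the 8 other motifs, 4 passed; 8 passed against shuffles, 1 with windows of 25 bp, 1 among summits over 500 bp from a start and 2 with the higher-signal IDR peaks. The cause was not tested.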

Other observations

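The tests in this part were all chosen after the data were seen.

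The peaks ranked 2 and 4 lie upstream of the microRNA gene mir-1 (2L, 20487441 to 20487531), which is expressed in muscle; it was singled out after its values were seen. Their summits lie 1191 and 6102 bp from the start of the gene, and 7 IDR summits lie within 10 kb of it. All 14 genes chosen from the Bearded and Enhancer of split groups, targets and modulators of Notch signalling, held an IDR peak against 5.35 ± 1.80 in length-matched random sets (two-sided permutation p = 0.0002, the smallest possible). The list was not meant to hold every member of these groups. They held 5.07 summits each against 0.654 ± 0.276. The list was chosen after the peak at rank 7 beside Ocho and Brd was seen, and the genes lie in 2 clusters and share peaks, so they are not 14 independent cases, the p-value is too small and the count is no test of the group. The 8 Hox genes held 5.50 summits each against 2.40 ± 1.11 (permutation p = 0.025), with 14 at Antp and 10 at Abd-B; all 8 had a peak, against 5.33 ± 1.34, which did not pass (permutation p = 0.081). These genes also lie in clusters. MSAmiP, one of the genes with the most summits, lies between abd-A and Abd-B. Summits in that cluster had thus been seen before the Hox list was chosen, so its p-values are no independent test.

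CACATG was followed by T in 51.7% of 1583 matches at summits (95% Wilson interval 49.3 to 54.2%) and in 27.3% of 359 matches in control windows (22.9 to 32.1%; two-sided Fisher exact p = 2.49e-17), and by A in 6.63% and 20.9%. This restates the high ratio of ACATGT, seen before, and is no separate test. The hypothesis that T is preferred after CACATG was therefore tested at the pooled summits outside the IDR list. There T followed in 37.5% of 2515 matches (95% Wilson interval 35.7 to 39.4%) and in 31.7% of 1306 matches in control windows (29.2 to 34.3%; two-sided Fisher exact p = 0.00036). Matches in 1 window are not independent, and both sets of summits come from the same libraries. Matches on both strands were counted. Where T and then G follow CACATG, the other strand also reads CACATG followed by T. Such a site is counted on each strand, which adds to T alone. The T shares in all these windows can therefore be too high and the Fisher p-values too small. Shares with such sites counted 1 time were not computed, so the size of the preference is uncertain.

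The hypothesis that tRNA genes attract peaks gave a negative result. Of 290 tRNA genes 19 had an IDR summit within 500 bp, 6.55% against 4.62% ± 1.63 in circular shifts (two-sided circular permutation p = 0.29).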
